A study of Mus musculus with 24 samples.

How the data were processed

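Poly(A)-selected RNA libraries that do not keep the strand (TruSeq, per the labels) were sequenced from sorted AT2 cells, whole lungs and AT2 organoids of mice; transcripts of overlapping genes on opposite strands cannot be told apart in such libraries. Per the labels, controls carried Sftpc-CreER and a tdTomato reporter, knockouts carried the conditional deletion of let-7a, let-7f and let-7d in addition, and all mice received tamoxifen. AT2 cells were sorted by flow cytometry and pooled from 3 mice per library according to the labels; the markers and gates of the sort are not given in the sources used here. Values were TPM (transcripts scaled to a fixed sum) computed by the authors, 1 table for each of the 4 kinds of sample, 24 libraries in all, and the processing notes in the labels name the GRCm38 genome; the aligner, the quantification tool and the gene models are not given in the sources used here. Each of the 4 tables listed 24972 gene symbols, and the library sums were 999919.8 to 999972.4 TPM. TPM keep no read numbers, so depth and counting error are unknown.

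Of the rows, 2 that shared a symbol with a row of higher mean were left out, and 26 symbols written as dates were kept as listed. Of 24970 unique symbols, 24464 matched gene names of GENCODE M21, which gave coordinates and 3′ UTRs. Each table was fitted alone with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with genotype as the only term, empirical Bayes moderation with a trend, two-sided tests and Benjamini-Hochberg adjustment over the genes tested; a gene was tested when at least as many libraries as the smaller group has held at least 1 TPM, and it passed at an adjusted p under 0.05. SE values are those of the moderated fit. No further scaling was applied in the reported values.

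The comparisons, tests, gene lists, naming rule and alternative settings were chosen before the data were examined. There were 39 lists, 22 of processes and 17 of cell type markers, and those with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison; with an estimated correlation no list passed in any comparison (smallest adjusted p 0.752 in AT2 cells, 0.192 and 0.113 in lungs at 6 days and 6 months and 0.902 in organoids). The directional test fry, which does not compare a list with other genes, called 2, 5, 23 and 0 lists. Genes whose longest annotated 3′ UTR (at least 50 bases, 20834 genes searched) holds the let-7 8mer CTACCTCA were compared with genes without the 7mers CTACCTC or TACCTCA, and with 100 shuffled 8mers. Differences between comparisons were contrasts of the within-table effects in 1 limma model over both tables, on genes past the filter in both. Shared calls were tested with Fisher's exact test, two-sided.

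Genes were named by rule: the 6 genes with the largest rise and the 6 with the largest fall that passed, had a mean of at least 5 TPM in the higher group and did not overlap between genotypes, passing over predicted genes and receptor segments; up to 4 members with the smallest adjusted p of each list described; and Sftpc, Hopx, Krt8, Hmga2, Igf2bp3, Lin28b, Bach1, Ezh2 and Myc throughout. Some genes that this rule selects are not reported here. Zfp169, Id1, Id2, Scgb1a1 and a few list members outside the smallest adjusted p values fall outside this rule and were chosen after their values were seen.

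The alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM, median-ratio scaling, quantile normalization, no variance trend, library weights, the replicate number as a block, leaving out each library in turn, the other list tests, 7mer sites and a threshold of 0.1 for shared calls. A separate spread for each table in the differences was added after the data were seen, because on simulated data the shared spread made 32 false calls of 230 and the separate spread 12 of 210. The fits were tested on simulated data: of genes changed by 1 on the log2 scale, 97% were recovered in AT2 cells, 58.2% in lungs at 6 days, 98.5% in lungs at 6 months and 40.3% in organoids, with 14 false calls of 212, 7 of 121, 7 of 213 and 9 of 97.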

Results

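RNA was sequenced from 24 mouse libraries in 4 kinds of sample. Each kind compared mice that carried a tamoxifen-induced deletion of the let-7a, let-7f and let-7d microRNA genes in alveolar type 2 (AT2) cells with control mice that carried the same Cre driver and tdTomato reporter. AT2 cells make surfactant and give rise to the flat alveolar type 1 (AT1) cells, and let-7 microRNAs lower the levels of transcripts that hold their sites. Flow-sorted AT2 cells were profiled 6 days after tamoxifen as pools of 3 mice, with 3 libraries per genotype. Whole lungs were profiled after 6 days (3 mice per genotype) and after 6 months of booster tamoxifen (4 mice per genotype). AT2 organoids were profiled after 14 days of culture (2 mice per genotype). The series asks what let-7 restrains in AT2 cells, with attention to intermediate cell states and to fibrosis. The values were TPM (transcripts scaled to one fixed sum per library), which keep no sequencing depth, so the depth of each library is unknown. The number of genes with at least 1 TPM was 11814 to 12178 per library in AT2 cells, 13620 to 14156 in lungs at 6 days, 13956 to 14175 in lungs at 6 months and 11925 to 12481 in organoids. The precursors Mirlet7a-1, Mirlet7f-1 and Mirlet7d were listed at 0 in all 24 libraries. Poly(A) libraries do not measure mature microRNAs, so these values do not check the genotype. All fold changes are log2 values of TPM + 1, knockout against control, which understates the change of genes with low TPM.

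In sorted AT2 cells 6 days after tamoxifen, the comparison asked what loss of let-7 changed in the cells that lost it. Cdc20, an activator of the anaphase-promoting complex, rose from 77.6 ± 2.96 TPM (SD, n = 3) in controls to 170.4 ± 4.86 TPM in knockouts, and Ccnb1, the mitotic cyclin B1, from 18.7 ± 1.03 to 38.2 ± 0.574 TPM. Some genes typical of alveolar macrophages rose from low levels, among them the scavenger receptor Marco (0.452 ± 0.177 to 11.1 ± 5.33 TPM) and the protease Ctsk (1.91 ± 0.523 to 21.5 ± 11.3 TPM). Hopx, a homeodomain gene marking AT1 cells, fell from 101 ± 23.9 to 62.0 ± 8.24 TPM. Sftpc, the surfactant protein C gene, took 146836 ± 7192 TPM in controls and 108055 ± 21761 TPM in knockouts and did not pass (log2 fold change −0.46 ± 0.72 SE, adjusted p 0.714).

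Of 40 cell cycle genes, 37 rose, 0 fell and 3 did not pass (40 rose and 0 fell when adjusted over the list alone). For cell cycle genes, the median was 0.81 (camera adjusted p 1.16e-25, and adjusted p = 0.752 with an estimated correlation). Birc5, which encodes the mitotic protein survivin (1.1 ± 0.09), and Rrm2, a subunit of ribonucleotide reductase (0.99 ± 0.09), were among those that rose. Of 36 reported let-7 targets, 7 rose, 0 fell and 29 did not pass (12 rose and 0 fell when adjusted over the list alone). For reported let-7 targets, the median was 0.28 (camera adjusted p 0.00432, and adjusted p = 0.752 with an estimated correlation). Among them were Gnptab (0.69 ± 0.12), which tags lysosomal enzymes, and the RAS family member Nras (0.61 ± 0.11). The histone methyltransferase Ezh2 (0.66 ± 0.12, adjusted p 0.0202) of Polycomb complex 2 rose too, but did not pass without control 2 (adjusted p 0.0736), control 3 (0.0515) or knockout 3 (0.0533). Of the other let-7 targets fixed for naming, Myc (0.48 ± 0.51, adjusted p 0.573) and Bach1 (−0.21 ± 0.11, adjusted p 0.254) did not pass. Hmga2 (0.329 ± 0.198 and 0.223 ± 0.102 TPM), Igf2bp3 and Lin28b lay below the filter of 1 TPM. Of 28 Polycomb genes, 2 rose, 1 fell and 25 did not pass (the same counts when adjusted over the list alone). As a list, Polycomb genes did not pass (camera adjusted p 0.875). Phf19 and Ezh2 rose and Cbx7 (−0.63 ± 0.12) fell. In the 494 tested genes whose 3′ UTR holds the let-7 8mer site, the mean log2 fold change exceeded that of 9428 genes without a let-7 7mer by 0.03. None (0) of 100 shuffled 8mers gave a difference as high, while the camera p against the genes without a site was 0.17.

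Some genes of several other programmes rose in the knockout AT2 cells. Of 38 Krt8-positive state genes, 11 rose, 0 fell and 27 did not pass (13 rose and 0 fell when adjusted over the list alone). For Krt8-positive state genes, the median was 0.35 (camera adjusted p 0.00219, and adjusted p = 0.752 with an estimated correlation). AT2 cells pass through this state after injury. The urokinase receptor gene Plaur (1.41 ± 0.23) and the tight junction gene Cldn4 (1.5 ± 0.32) rose, and Krt8 (0.30 ± 0.19, adjusted p 0.348) itself did not pass. Of 25 BACH1 and NRF2 targets, 5 rose, 0 fell and 20 did not pass (8 rose and 0 fell when adjusted over the list alone). For BACH1 and NRF2 targets, the median was 0.37 (camera adjusted p 0.00066, and adjusted p = 0.752 with an estimated correlation). BACH1 and NRF2 regulate haem and oxidant defence genes, of which the haem oxygenase Hmox1 (0.94 ± 0.16) and the cystine transporter Slc7a11 (1.73 ± 0.30) rose. Of 26 collagen and matrix genes, 8 rose, 0 fell and 18 did not pass (16 rose and 0 fell when adjusted over the list alone). For collagen and matrix genes, the median was 0.61 (camera adjusted p 3.05e-05, and adjusted p = 0.752 with an estimated correlation). Elastin, Eln (1.64 ± 0.26), and Col6a2 (0.81 ± 0.13) were among them. Of 18 genes of epithelial to mesenchymal transition, 4 rose, 0 fell and 14 did not pass (8 rose and 0 fell when adjusted over the list alone). Their median was 0.43 (camera adjusted p 0.0039, and adjusted p = 0.752 with an estimated correlation). Of 37 oxidative phosphorylation genes, 3 rose, 0 fell and 34 did not pass (8 rose and 0 fell when adjusted over the list alone). For oxidative phosphorylation genes, the median was 0.17 (camera adjusted p 0.0124, and adjusted p = 0.811 with an estimated correlation). That call ended without control 2 (adjusted p 0.0978) or knockout 1 (0.134). Of 35 MYC target and ribosome biogenesis genes, 0 passed by limma (the same counts when adjusted over the list alone), and 34 had positive values. Their median was 0.27 (camera adjusted p 0.00848, and adjusted p = 0.811 with an estimated correlation). The MYC target call ended without knockout 1 (0.195), whose ribosomal protein genes took 13.97% of TPM against 7.83% to 9.13% in the other 5 libraries.

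The camera direction was lower for other lists. Of 25 AT1 markers, 2 rose, 2 fell and 21 did not pass (the same counts when adjusted over the list alone). For AT1 markers, the median was −0.23 (camera adjusted p 0.000893, and adjusted p = 0.752 with an estimated correlation). Igfbp2, a binding protein of insulin-like growth factors (−1.23 ± 0.24), and Hopx (−0.68 ± 0.17, adjusted p 0.0472) fell, and Tspan8 (0.95 ± 0.09) and podoplanin, Pdpn (0.76 ± 0.12), rose. The Hopx call ended without the filter, under quantile normalization and without a variance trend. It also ended without control 1 (adjusted p 0.103), control 2 (0.128), knockout 1 (0.0936) or knockout 3 (0.144). Of 20 AP-1 and immediate early genes, 0 rose, 2 fell and 18 did not pass (0 rose and 5 fell when adjusted over the list alone). For AP-1 and immediate early genes, the median was −0.41 (camera adjusted p 2.67e-05, and adjusted p = 0.752 with an estimated correlation). Zfp36 (−0.67 ± 0.15) and Btg2 (−0.76 ± 0.19) fell. Of 31 fatty acid and cholesterol synthesis genes, 0 passed by limma (the same counts when adjusted over the list alone), and 9 had positive values. For fatty acid and cholesterol synthesis genes, the median was −0.25 (camera adjusted p 4.59e-05, and adjusted p = 0.752 with an estimated correlation). Of 22 heat shock and unfolded protein genes, 0 rose, 1 fell and 21 did not pass (the same counts when adjusted over the list alone). For heat shock and unfolded protein genes, the median was −0.12 (camera adjusted p 0.0124, and adjusted p = 0.752 with an estimated correlation). The 1 gene that fell was Herpud1 (−0.81 ± 0.10), and the call ended without control 3 (adjusted p 0.559) or knockout 2 (0.158), and after quantile normalization (0.0998). Of 30 AT2 identity and surfactant genes, 1 rose, 0 fell and 29 did not pass (2 rose and 1 fell when adjusted over the list alone). For AT2 identity and surfactant genes, the median was −0.04 (camera adjusted p 0.0452, and adjusted p = 0.811 with an estimated correlation). The 1 gene that rose was Muc1, a membrane mucin (0.47 ± 0.11), while the list passed as lower. That call ended without control 1 (adjusted p 0.115), control 3 (0.0661) or knockout 1 (0.781), under both scalings (0.0873 and 0.388), without the filter (0.107), with library weights (0.217) and with the replicate block (0.0846).

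Markers of cell types outside the sort also moved. Of 13 alveolar macrophage markers, 6 rose, 0 fell and 7 did not pass (10 rose and 0 fell when adjusted over the list alone). For alveolar macrophage markers, the median was 1.02 (camera adjusted p 2.67e-05, and adjusted p = 0.752 with an estimated correlation). Chil3, a chitinase-like secreted protein, rose from 25.9 ± 10.1 to 146 ± 62.8 TPM. Of 21 chemokine, cytokine and receptor genes, 5 rose, 0 fell and 16 did not pass (8 rose and 0 fell when adjusted over the list alone). For chemokine, cytokine and receptor genes, the median was 0.84 (camera adjusted p 0.0103, and adjusted p = 0.752 with an estimated correlation). The acute phase gene Saa3 (2.12 ± 0.21), Ccl6 (1.75 ± 0.29) and the siderophore-binding Lcn2 (1.4 ± 0.24) were among them. That call ended without control 2 (adjusted p 0.0707) or knockout 3 (0.0523). Of 5 erythrocyte genes, 2 rose, 0 fell and 3 did not pass (the same counts when adjusted over the list alone). As a list, erythrocyte genes did not pass (camera adjusted p 0.637). The haemoglobin genes Hba-a1 (2.08 ± 0.38) and Hbb-bt (3.26 ± 0.78) rose, and the list median was 0.02. Of 12 fibroblast genes, 1 rose, 0 fell and 11 did not pass (2 rose and 1 fell when adjusted over the list alone). As a list, fibroblast genes did not pass (camera adjusted p 0.41). Of the fibroblast genes 10 had positive values, with a median of 0.47, and the list passed without control 1 (0.00105). Of 5 neutrophil genes, 1 rose, 0 fell and 4 did not pass (2 rose and 0 fell when adjusted over the list alone). As a list, neutrophil genes did not pass (camera adjusted p 0.0786). All 5 neutrophil genes had positive values, with a median of 0.96. That list passed as higher without the filter (0.00884), under both scalings (0.0361 and 0.0276), with the replicate block (0.031) and without control 1 (0.000685), control 3 (0.0253) or knockout 2 (0.0271). Of 14 interstitial macrophage and monocyte genes, 1 rose, 0 fell and 13 did not pass (the same counts when adjusted over the list alone). As a list, interstitial macrophage and monocyte genes did not pass (camera adjusted p 0.423). Their median was 0.47. The club cell and basal cell lists (medians −0.02 and 0.77) did not pass (camera adjusted p 0.101 and 0.41), but the first passed as lower without control 2 (0.00129) and the second as higher without control 3 (0.0116). Of 9 ciliated cell genes, 0 passed by limma (the same counts when adjusted over the list alone), and 1 had positive values. For ciliated cell genes, the median was −0.28 (camera adjusted p 0.0163, and adjusted p = 0.752 with an estimated correlation). That call ended without control 1 (adjusted p 0.597) or knockout 1 (0.134), under both scalings (0.0873 and 0.0777) and with library weights (0.0591). The mesothelial list (median 0.29, mean −0.05) and the endothelial list (median 0.10, mean 0.12, camera direction lower) did not pass (camera adjusted p 0.745 and 0.837). The endothelial list passed as higher without control 1 (0.000648). Among genes named for size, the acute phase gene Orm1 (3.35 ± 0.26), the sodium pump modulator Fxyd4 (2.93 ± 0.52) and the lectin receptor Clec4n (2.91 ± 0.32) rose. Vpreb3 (−1.71 ± 0.27), the complement inhibitor gene Cd59a (−1.4 ± 0.23), Rab6b (−1.26 ± 0.27), the lipase Mgll (−1.23 ± 0.20) and the WNT inhibitor Notum (−1.2 ± 0.24) fell, as did Igfbp2.

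By limma, 802 genes rose and 148 fell of 12109 tested in AT2 cells (84.4% of calls higher; 67.7% after median-ratio scaling and 65% after quantile normalization), and the genotypes did not overlap in 4086 genes (33.7%, where chance gives 10%). The counts fell to 306 higher and 42 lower without control 1, 181 and 6 without control 2, 268 and 26 without control 3, 439 and 62 without knockout 1, and 213 and 23 without knockout 3. Without knockout 2, 285 were lower. Of 75 named genes that passed, 39, 54 and 35 no longer passed without control 1, 2 or 3, and 28, 10 and 54 without knockout 1, 2 or 3.

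In whole lungs 6 days after tamoxifen, the comparison asked how the tissue differed soon after the deletion. Among the genes that were far higher in knockouts, Marco rose from 19.1 ± 20.9 to 365.8 ± 69.3 TPM (SD, n = 3), Hmox1 from 135 ± 136 to 2210 ± 476 TPM, and osteopontin, Spp1, from 164 ± 27.9 to 3561 ± 2259 TPM. Sftpc fell from 31418 ± 2477 to 11265 ± 1711 TPM (−1.49 ± 0.14, adjusted p 0.00383; not past the threshold after median-ratio scaling, where it was −1.34), and the club cell secretoglobin Scgb1a1 from 154929 ± 11408 to 75796 ± 7746 TPM. The median log2 fold change of all genes tested was −0.14, and a library with a high share of haemoglobin transcripts, knockout 3 (12.64% of TPM, against 1.40% to 6.54% in the other 5), stood apart from the other knockouts.

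Of 25 BACH1 and NRF2 targets, 13 rose, 0 fell and 12 did not pass (18 rose and 0 fell when adjusted over the list alone). For BACH1 and NRF2 targets, the median was 0.65 (camera adjusted p 5.84e-14, and adjusted p = 0.451 with an estimated correlation). The ferritin genes Ftl1 (2.09 ± 0.25) and Fth1 (1.6 ± 0.20) rose, and Bach1 (−0.16 ± 0.17, adjusted p 0.571) itself did not pass. Of 38 Krt8-positive state genes, 11 rose, 0 fell and 27 did not pass (21 rose and 0 fell when adjusted over the list alone). For Krt8-positive state genes, the median was 0.66 (camera adjusted p 1.16e-14, and adjusted p = 0.481 with an estimated correlation). Among them were Spp1 (4.26 ± 0.39), the stress cytokine Gdf15 (3.03 ± 0.29), galectin-3, Lgals3 (1.72 ± 0.24), and Sfn (1.66 ± 0.24). Krt8 did not pass (0.67 ± 0.19, adjusted p 0.0688), and did after median-ratio scaling (0.81), quantile normalization (0.56), library weights (0.97) or without knockout 3 (0.84). Of 40 cell cycle genes, 2 rose, 0 fell and 38 did not pass (12 rose and 0 fell when adjusted over the list alone). For cell cycle genes, the median was 0.83 (camera adjusted p 1.16e-14, and adjusted p = 0.674 with an estimated correlation). Ccne1 (1.05 ± 0.23) and Ccnb1 (1.29 ± 0.30) rose, and all 40 values were positive. Of 32 chemokine, cytokine and receptor genes, 10 rose, 0 fell and 22 did not pass (14 rose and 1 fell when adjusted over the list alone). For chemokine, cytokine and receptor genes, the median was 0.64 (camera adjusted p 2.33e-06, and adjusted p = 0.481 with an estimated correlation). Lcn2 (1.96 ± 0.28), Ccl6 (2.06 ± 0.31) and the alarmin Il33 (1.21 ± 0.21) rose. Of 27 glycolysis and hypoxia genes, 8 rose, 0 fell and 19 did not pass (11 rose and 0 fell when adjusted over the list alone). For glycolysis and hypoxia genes, the median was 0.24 (camera adjusted p 1.81e-06, and adjusted p = 0.481 with an estimated correlation). Ankrd37 (2.25 ± 0.18) and the enzyme gene Pgam1 (0.90 ± 0.15) rose. Of 40 collagen and matrix genes, 4 rose, 2 fell and 34 did not pass (7 rose and 2 fell when adjusted over the list alone). For collagen and matrix genes, the median was 0.29 (camera adjusted p 0.000183, and adjusted p = 0.696 with an estimated correlation). The protease inhibitor Timp1 (2.56 ± 0.46) rose and the proteoglycan gene Dcn (−1.48 ± 0.24) fell.

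Further lists were tested in the 6-day lungs. Of 37 oxidative phosphorylation genes, 1 rose, 0 fell and 36 did not pass (the same counts when adjusted over the list alone). For oxidative phosphorylation genes, the median was 0.19 (camera adjusted p 1.11e-05, and adjusted p = 0.481 with an estimated correlation). Cox5a (0.66 ± 0.14) rose, and the call ended after quantile normalization (adjusted p 0.0682). Of 22 senescence-associated genes, 5 rose, 3 fell and 14 did not pass (9 rose and 3 fell when adjusted over the list alone). For senescence-associated genes, the median was 0.42 (camera adjusted p 0.000627, and adjusted p = 0.696 with an estimated correlation). Of 35 MYC target and ribosome biogenesis genes, 2 rose, 0 fell and 33 did not pass (the same counts when adjusted over the list alone). For MYC target and ribosome biogenesis genes, the median was 0.20 (camera adjusted p 0.00112, and adjusted p = 0.696 with an estimated correlation). Eif4a1 (0.60 ± 0.13) and Ldha (0.55 ± 0.12) rose. Of 30 p53 targets, 4 rose, 1 fell and 25 did not pass (6 rose and 3 fell when adjusted over the list alone). For p53 targets, the median was 0.18 (camera adjusted p 0.00836, and adjusted p = 0.696 with an estimated correlation). Plk3 (1.38 ± 0.24) and the apoptosis gene Bax (0.80 ± 0.14) rose. Of 21 AP-1 and immediate early genes, 1 rose, 0 fell and 20 did not pass (2 rose and 0 fell when adjusted over the list alone). For AP-1 and immediate early genes, the median was 0.14 (camera adjusted p 0.01, and adjusted p = 0.738 with an estimated correlation). Socs3 (1.14 ± 0.27) rose, and the call ended without control 1 (adjusted p 0.0558) or control 3 (0.058), and after quantile normalization (0.0682). Of 23 genes of epithelial to mesenchymal transition, 1 rose, 0 fell and 22 did not pass (4 rose and 2 fell when adjusted over the list alone). For genes of epithelial to mesenchymal transition, the median was 0.32 (camera adjusted p 0.0327, and adjusted p = 0.819 with an estimated correlation). The call for this list ended without control 1 (adjusted p 0.0662) or knockout 1 (0.191), without the filter (0.076) and after quantile normalization (0.261). Of 42 reported let-7 targets, 1 rose, 0 fell and 41 did not pass (the same counts when adjusted over the list alone). As a list, reported let-7 targets did not pass (camera adjusted p 0.81). The let-7 target median was −0.15, the mean −0.06 and the camera direction higher, and Gatm, an enzyme of creatine synthesis (1.23 ± 0.24), rose. Of the other genes fixed for naming, Myc (0.69 ± 0.19, adjusted p 0.0667), Ezh2 (0.48 ± 0.22, adjusted p 0.214) and Hopx (−0.08 ± 0.15, adjusted p 0.751) did not pass, and Hmga2, Igf2bp3 and Lin28b lay below the filter. Myc did pass after median-ratio scaling (0.82), quantile normalization (0.85), library weights (0.79) or without knockout 3 (0.75), and Ezh2 after quantile normalization (0.63) or library weights (0.80). Of 30 AT2 identity and surfactant genes, 2 rose, 2 fell and 26 did not pass (4 rose and 5 fell when adjusted over the list alone). As a list, AT2 identity and surfactant genes did not pass (camera adjusted p 0.912). That list passed as lower after quantile normalization (0.047). Sftpd, a surfactant gene (0.59 ± 0.11), rose and Etv5, a transcription factor of AT2 cells (−0.75 ± 0.16), fell. Of 25 AT1 markers, 2 rose, 0 fell and 23 did not pass (2 rose and 2 fell when adjusted over the list alone). As a list, AT1 markers did not pass (camera adjusted p 0.81).

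Of 11 heart and skeletal muscle genes, 0 rose, 11 fell and 0 did not pass (the same counts when adjusted over the list alone). Their median was −2.53 (camera adjusted p 4.37e-11, and adjusted p = 0.451 with an estimated correlation). Cardiac actin, Actc1, fell from 313 ± 51.5 to 53.1 ± 1.64 TPM and the heart muscle myosin Myh6 from 100.4 ± 17.3 to 9.48 ± 2.9 TPM. Of 15 club cell genes, 0 rose, 9 fell and 6 did not pass (0 rose and 10 fell when adjusted over the list alone). For club cell genes, the median was −1.03 (camera adjusted p 1.19e-06, and adjusted p = 0.192 with an estimated correlation). The cytochrome Cyp2f2 (−2.05 ± 0.19) and Aldh1a1 (−1.15 ± 0.11) fell. Of 15 ciliated cell genes, 0 rose, 6 fell and 9 did not pass (0 rose and 15 fell when adjusted over the list alone). For ciliated cell genes, the median was −0.72 (camera adjusted p 2.12e-07, and adjusted p = 0.451 with an estimated correlation). Tppp3 (−1.19 ± 0.15) and Hydin (−1.06 ± 0.21) fell. Of 20 fibroblast genes, 0 rose, 5 fell and 15 did not pass (0 rose and 8 fell when adjusted over the list alone). For fibroblast genes, the median was −0.74 (camera adjusted p 0.000304, and adjusted p = 0.696 with an estimated correlation). Inmt (−1.54 ± 0.13) and gelsolin, Gsn (−1.63 ± 0.27), fell. Of 19 endothelial genes, 0 rose, 1 fell and 18 did not pass (0 rose and 8 fell when adjusted over the list alone). For endothelial genes, the median was −0.86 (camera adjusted p 0.00132, and adjusted p = 0.696 with an estimated correlation). The 1 gene that fell was Lyve1 (−1.24 ± 0.27). Of 17 T and NK cell genes, 0 rose, 2 fell and 15 did not pass (0 rose and 7 fell when adjusted over the list alone). For T and NK cell genes, the median was −0.62 (camera adjusted p 0.00112, and adjusted p = 0.696 with an estimated correlation). Nkg7 (−0.95 ± 0.22) and the granzyme Gzma (−1.03 ± 0.24) fell. Of 15 smooth muscle and pericyte genes, 0 rose, 4 fell and 11 did not pass (1 rose and 7 fell when adjusted over the list alone). For smooth muscle and pericyte genes, the median was −0.67 (camera adjusted p 0.0327, and adjusted p = 0.738 with an estimated correlation). Lgr6 (−1.23 ± 0.18) and calponin, Cnn1 (−1.5 ± 0.23), fell, and the call ended without knockout 2 (adjusted p 0.126) and with a filter at 5 TPM (0.0685).

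Genes of the immune cell lists moved both ways at 6 days. Of 18 alveolar macrophage markers, 6 rose, 4 fell and 8 did not pass (7 rose and 4 fell when adjusted over the list alone). For alveolar macrophage markers, the median was 0.06 (camera adjusted p 0.0194, and adjusted p = 0.696 with an estimated correlation). Ctsk (3.87 ± 0.34) and Chil3 (2.8 ± 0.45) rose and the lipid carrier Fabp1 (−2.79 ± 0.39) fell, and the mean of the list was 0.60. That call ended without control 2 (adjusted p 0.0792) or knockout 3 (0.452), under both scalings (0.0999 and 0.144) and with library weights (0.986). Of 20 interstitial macrophage and monocyte genes, 4 rose, 1 fell and 15 did not pass (8 rose and 2 fell when adjusted over the list alone). For interstitial macrophage and monocyte genes, the median was 0.53 (camera adjusted p 2.44e-05, and adjusted p = 0.589 with an estimated correlation). Ms4a7 (1.49 ± 0.20) and the complement gene C1qb (1.14 ± 0.22) rose. Of 14 neutrophil genes, 2 rose, 0 fell and 12 did not pass (the same counts when adjusted over the list alone). For neutrophil genes, the median was 0.07 (camera adjusted p 0.0339, and adjusted p = 0.696 with an estimated correlation). Mmp8 (1.56 ± 0.17) and Clec4d (2.12 ± 0.33) rose. Of 8 erythrocyte genes, 0 passed by limma (the same counts when adjusted over the list alone), and 8 had positive values. For erythrocyte genes, the median was 0.93 (camera adjusted p 0.0125, and adjusted p = 0.696 with an estimated correlation). The neutrophil and erythrocyte calls ended without control 2 (adjusted p 0.2 and 0.254) or knockout 3 (0.708 and 0.623), and after median-ratio scaling (0.126 and 0.102) or quantile normalization (0.155 and 0.179). The neutrophil call also ended without the filter (0.0806), with a filter at 5 TPM (0.0867) and with library weights (0.529). Among genes named for size, arginase 1, Arg1 (4.73 ± 0.48), and Clec4n (3.65 ± 0.44) rose. Bpifa1, a secreted airway protein (−4.53 ± 0.86), the atrial hormone gene Nppa (−4.25 ± 0.80) and the fat cell genes Car3 (−4.33 ± 0.50), Cfd (−4.14 ± 0.54), Retn (−3.72 ± 0.54) and Adipoq (−3.68 ± 0.51) fell.

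By limma, 447 genes rose and 536 fell of 14154 tested in lungs at 6 days (45.5% of calls higher), and the genotypes did not overlap in 5119 genes (36.2%, where chance gives 10%). After median-ratio scaling 906 rose and 883 fell (50.6% higher) and the median log2 fold change of all genes was −0.01, and after quantile normalization 922 rose and 966 fell (48.8% higher). The counts were 41 higher and 51 lower without control 1, 68 and 80 without control 3, 180 and 172 without knockout 2 and 1032 and 1017 without knockout 3. They were 251 lower without control 2 and 976 lower without knockout 1. Weighting the libraries gave 3858 and 4537. Of 92 named genes that passed, 68, 24 and 61 no longer passed without control 1, 2 or 3, and 9, 46 and 4 without knockout 1, 2 or 3.

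In whole lungs after 6 months of booster tamoxifen, the comparison asked what lasting loss of let-7 left in the tissue. Several genes typical of macrophages were many times higher. The macrophage elastase Mmp12 rose from 3.71 ± 1.37 to 555.7 ± 162 TPM (SD, n = 4), Gpnmb from 11.1 ± 1.91 to 1215 ± 390 TPM, and Trem2, a lipid-sensing receptor, from 7.10 ± 0.912 to 206.9 ± 45.5 TPM. Npy, a neuropeptide gene, was listed at 0 in all 4 controls and at 69.7 ± 28.7 TPM in knockouts. The chitinase-like Chil1, an AT2 gene, rose from 783 ± 20.3 to 2905 ± 293 TPM. Hopx fell from 1272 ± 116 to 764 ± 96.0 TPM and Sftpc did not pass (15476 ± 596 and 17627 ± 1846 TPM; 0.18 ± 0.08, adjusted p 0.105). It passed without knockout 4 (0.24, adjusted p 0.0331).

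Of 30 AT2 identity and surfactant genes, 20 rose, 0 fell and 10 did not pass (22 rose and 0 fell when adjusted over the list alone). For AT2 identity and surfactant genes, the median was 0.53 (camera adjusted p 1.04e-10, and adjusted p = 0.235 with an estimated correlation). Lysozyme, Lyz2 (1.15 ± 0.07), the cathepsin Ctsh (0.80 ± 0.05) and Sftpd (1.03 ± 0.06) rose. Whole-lung RNA does not tell its cell of origin, and alveolar macrophage markers had a median of 1.55 here. So no list, here or in lungs at 6 days, can show a gain within AT2 cells. Of 25 AT1 markers, 3 rose, 8 fell and 14 did not pass (3 rose and 10 fell when adjusted over the list alone). For AT1 markers, the median was −0.14 (camera adjusted p 0.0176, and adjusted p = 0.655 with an estimated correlation). Emp2 (−0.52 ± 0.05), the caveolin Cav1 (−0.55 ± 0.06) and Hopx (−0.74 ± 0.09) fell, and the call ended without control 1 (adjusted p 0.0653). Of 25 BACH1 and NRF2 targets, 21 rose, 1 fell and 3 did not pass (22 rose and 1 fell when adjusted over the list alone). For BACH1 and NRF2 targets, the median was 0.66 (camera adjusted p 6.17e-14, and adjusted p = 0.113 with an estimated correlation). Ftl1 (2.13 ± 0.08), Fth1 (1.21 ± 0.06) and the peroxidase Prdx1 (1.31 ± 0.06) rose. Bach1 itself rose slightly (0.26 ± 0.08, adjusted p 0.0257). It did not pass without control 1 (adjusted p 0.07), control 2 (0.0623), knockout 1 (0.0619), knockout 2 (0.0594) or knockout 3 (0.0628). Of 37 Krt8-positive state genes, 16 rose, 2 fell and 19 did not pass (17 rose and 4 fell when adjusted over the list alone). For Krt8-positive state genes, the median was 0.16 (camera adjusted p 0.000365, and adjusted p = 0.235 with an estimated correlation). Lgals3 (2.99 ± 0.08), Gdf15 (3.57 ± 0.12), Spp1 (2.79 ± 0.17) and the calcium-binding S100a11 (0.53 ± 0.05) rose, and Krt8 (−0.11 ± 0.05, adjusted p 0.15) did not pass, except after quantile normalization (−0.22). Of 32 fatty acid and cholesterol synthesis genes, 19 rose, 1 fell and 12 did not pass (the same counts when adjusted over the list alone). For fatty acid and cholesterol synthesis genes, the median was 0.29 (camera adjusted p 7.17e-07, and adjusted p = 0.311 with an estimated correlation). The sterol enzymes Dhcr7 (1.41 ± 0.10), Mvd (1.25 ± 0.09) and Cyp51 (0.82 ± 0.06) rose. Of 30 chemokine, cytokine and receptor genes, 20 rose, 1 fell and 9 did not pass (the same counts when adjusted over the list alone). For chemokine, cytokine and receptor genes, the median was 0.78 (camera adjusted p 3.26e-08, and adjusted p = 0.113 with an estimated correlation). Ccl6 (4.04 ± 0.12), Lcn2 (3.43 ± 0.13), Il1rn (2.83 ± 0.14) and Il33 (1.39 ± 0.09) rose.

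Collagen and matrix genes moved both ways at 6 months. Of 40 collagen and matrix genes, 11 rose, 12 fell and 17 did not pass (12 rose and 13 fell when adjusted over the list alone). As a list, collagen and matrix genes did not pass (camera adjusted p 0.852). Their median was −0.02 and their mean 0.05, with fibronectin, Fn1 (0.58 ± 0.06), higher and transgelin, Tagln (−0.82 ± 0.09), lower. Of 27 TGF-beta response genes, 9 rose, 5 fell and 13 did not pass (10 rose and 8 fell when adjusted over the list alone). As a list, TGF-beta response genes did not pass (camera adjusted p 0.349). The ligand gene Tgfb1 (0.68 ± 0.07) rose. Of 42 reported let-7 targets, 9 rose, 5 fell and 28 did not pass (the same counts when adjusted over the list alone). As a list, reported let-7 targets did not pass (camera adjusted p 0.852). The median (−0.04) and mean (0.06) of this list differed in sign. The TGF-beta receptor Tgfbr1 (0.94 ± 0.09), Gnptab (0.87 ± 0.09), Rgs16 (1.09 ± 0.18) and Myc (0.67 ± 0.12, adjusted p 0.00129) rose, and Ezh2 (0.10 ± 0.15, adjusted p 0.668) did not pass. Hmga2, Igf2bp3 and Lin28b lay below the filter. Of 37 cell cycle genes, 5 rose, 0 fell and 32 did not pass (4 rose and 0 fell when adjusted over the list alone). For cell cycle genes, the median was 0.19 (camera adjusted p 0.0198, and adjusted p = 0.741 with an estimated correlation). Pcna, the sliding clamp of DNA replication (0.34 ± 0.05), rose. The cell cycle call ended without control 1 (adjusted p 0.0653), control 3 (0.0967) or knockout 4 (0.065), and with a filter at 5 TPM (0.0881). Of 37 oxidative phosphorylation genes, 8 rose, 1 fell and 28 did not pass (the same counts when adjusted over the list alone). For oxidative phosphorylation genes, the median was 0.10 (camera adjusted p 0.0224, and adjusted p = 0.658 with an estimated correlation). Cox5a (0.43 ± 0.06) rose and Ndufa5 (−0.41 ± 0.08) fell. That call ended without control 3 (adjusted p 0.0967), control 4 (0.0569), knockout 2 (0.0651) or knockout 4 (0.0516), and under both scalings (0.0512 and 0.935). Of 27 glycolysis and hypoxia genes, 14 rose, 3 fell and 10 did not pass (the same counts when adjusted over the list alone). For glycolysis and hypoxia genes, the median was 0.25 (camera adjusted p 0.00536, and adjusted p = 0.311 with an estimated correlation). Pgam1 (0.79 ± 0.06) rose. Of 14 imprinted and fetal growth genes, 2 rose, 7 fell and 5 did not pass (2 rose and 8 fell when adjusted over the list alone). For imprinted and fetal growth genes, the median was −0.34 (camera adjusted p 0.0397, and adjusted p = 0.55 with an estimated correlation). Igf2 (−0.73 ± 0.13) fell and the cell cycle inhibitor gene Cdkn1c (1.36 ± 0.19) rose. The imprinted gene call ended without control 2 (adjusted p 0.066), knockout 3 (0.0636) or knockout 4 (0.0516), without the filter (0.224), with a filter at 5 TPM (0.147) and with library weights (0.051).

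Of 19 endothelial genes, 0 rose, 16 fell and 3 did not pass (the same counts when adjusted over the list alone). For endothelial genes, the median was −0.44 (camera adjusted p 1.76e-08, and adjusted p = 0.213 with an estimated correlation). Claudin 5, Cldn5 (−0.98 ± 0.06), the cadherin Cdh5 (−0.59 ± 0.05), the endothelin receptor Ednrb (−1.71 ± 0.12) and the VEGF receptor Kdr (−1.07 ± 0.10) fell. Of 20 fibroblast genes, 1 rose, 13 fell and 6 did not pass (1 rose and 14 fell when adjusted over the list alone). For fibroblast genes, the median was −0.50 (camera adjusted p 8.49e-06, and adjusted p = 0.113 with an estimated correlation). Pdgfra (−1.01 ± 0.08), Gsn (−0.67 ± 0.06) and Npnt (−0.55 ± 0.05) fell. Of 15 smooth muscle and pericyte genes, 0 rose, 12 fell and 3 did not pass (0 rose and 13 fell when adjusted over the list alone). For smooth muscle and pericyte genes, the median was −0.78 (camera adjusted p 3.05e-08, and adjusted p = 0.113 with an estimated correlation). Smooth muscle myosin, Myh11 (−1.05 ± 0.10), and Acta2 (−0.92 ± 0.10) fell. Of 15 ciliated cell genes, 0 rose, 14 fell and 1 did not pass (the same counts when adjusted over the list alone). For ciliated cell genes, the median was −0.55 (camera adjusted p 3.05e-08, and adjusted p = 0.213 with an estimated correlation). Tppp3 (−0.70 ± 0.06) fell. Of 15 club cell genes, 0 rose, 11 fell and 4 did not pass (0 rose and 12 fell when adjusted over the list alone). For club cell genes, the median was −0.67 (camera adjusted p 1.44e-07, and adjusted p = 0.213 with an estimated correlation). Cyp2f2 (−1.1 ± 0.05) and Scgb3a2 (−1.13 ± 0.09) fell. Of 11 heart and skeletal muscle genes, 0 rose, 10 fell and 1 did not pass (the same counts when adjusted over the list alone). For heart and skeletal muscle genes, the median was −1.22 (camera adjusted p 8.49e-06, and adjusted p = 0.321 with an estimated correlation). Actc1 (−1.25 ± 0.15) and Myh6 (−1.48 ± 0.23) fell. Of 9 mesothelial genes, 0 rose, 7 fell and 2 did not pass (1 rose and 8 fell when adjusted over the list alone). For mesothelial genes, the median was −0.59 (camera adjusted p 0.000308, and adjusted p = 0.235 with an estimated correlation). Igfbp6 (−1.0 ± 0.08) and Upk3b (−0.94 ± 0.12) fell.

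Genes of the immune cell lists moved in several directions at 6 months. Of 18 alveolar macrophage markers, 12 rose, 4 fell and 2 did not pass (the same counts when adjusted over the list alone). For alveolar macrophage markers, the median was 1.55 (camera adjusted p 9.23e-06, and adjusted p = 0.311 with an estimated correlation). Ctsk (4.66 ± 0.13), the lysosomal proton pump subunit Atp6v0d2 (4.28 ± 0.13) and the integrin Itgax (3.17 ± 0.10) rose. Of 20 interstitial macrophage and monocyte genes, 10 rose, 2 fell and 8 did not pass (10 rose and 3 fell when adjusted over the list alone). For interstitial macrophage and monocyte genes, the median was 0.49 (camera adjusted p 0.00344, and adjusted p = 0.311 with an estimated correlation). Adgre1 (1.91 ± 0.08), Ms4a7 (2.97 ± 0.16), Apoe (1.46 ± 0.10) and C1qb (1.62 ± 0.14) rose. Of 14 neutrophil genes, 3 rose, 1 fell and 10 did not pass (the same counts when adjusted over the list alone). As a list, neutrophil genes did not pass (camera adjusted p 0.146). Clec4d (3.91 ± 0.14) rose and Mmp9 (−0.68 ± 0.14) fell. Of 17 T and NK cell genes, 2 rose, 6 fell and 9 did not pass (2 rose and 8 fell when adjusted over the list alone). For T and NK cell genes, the median was −0.37 (camera adjusted p 0.0351, and adjusted p = 0.685 with an estimated correlation). The granzymes Gzma (−2.07 ± 0.25) and Gzmb (−1.67 ± 0.19) fell and the cytokine receptor Il7r (1.65 ± 0.18) rose, and the call ended without control 4 (adjusted p 0.166) or knockout 2 (0.0576), with a filter at 5 TPM (0.147), after quantile normalization (0.104) and with the replicate block (0.0579). Among genes named for size, Ear6 (5.0 ± 0.21) and the chemokine receptor Cxcr1 (4.91 ± 0.22) rose. Spon2 (−2.41 ± 0.17), Gvin1 (−2.22 ± 0.62), Fibin (−2.16 ± 0.08), Cst8 (−2.15 ± 0.20) and the peptidase Xpnpep2 (−2.14 ± 0.11) fell.

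By limma, 2260 genes rose and 1966 fell of 14177 tested in lungs at 6 months (53.5% of calls higher; 42.6% after quantile normalization), and the genotypes did not overlap in 4333 genes (30.6%, where chance gives 2.86%). Of 145 named genes that passed, 3 to 7 no longer passed without any one library: 5, 7, 3 and 4 without controls 1 to 4 and 5, 7, 5 and 4 without knockouts 1 to 4.

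**Figure D1:**
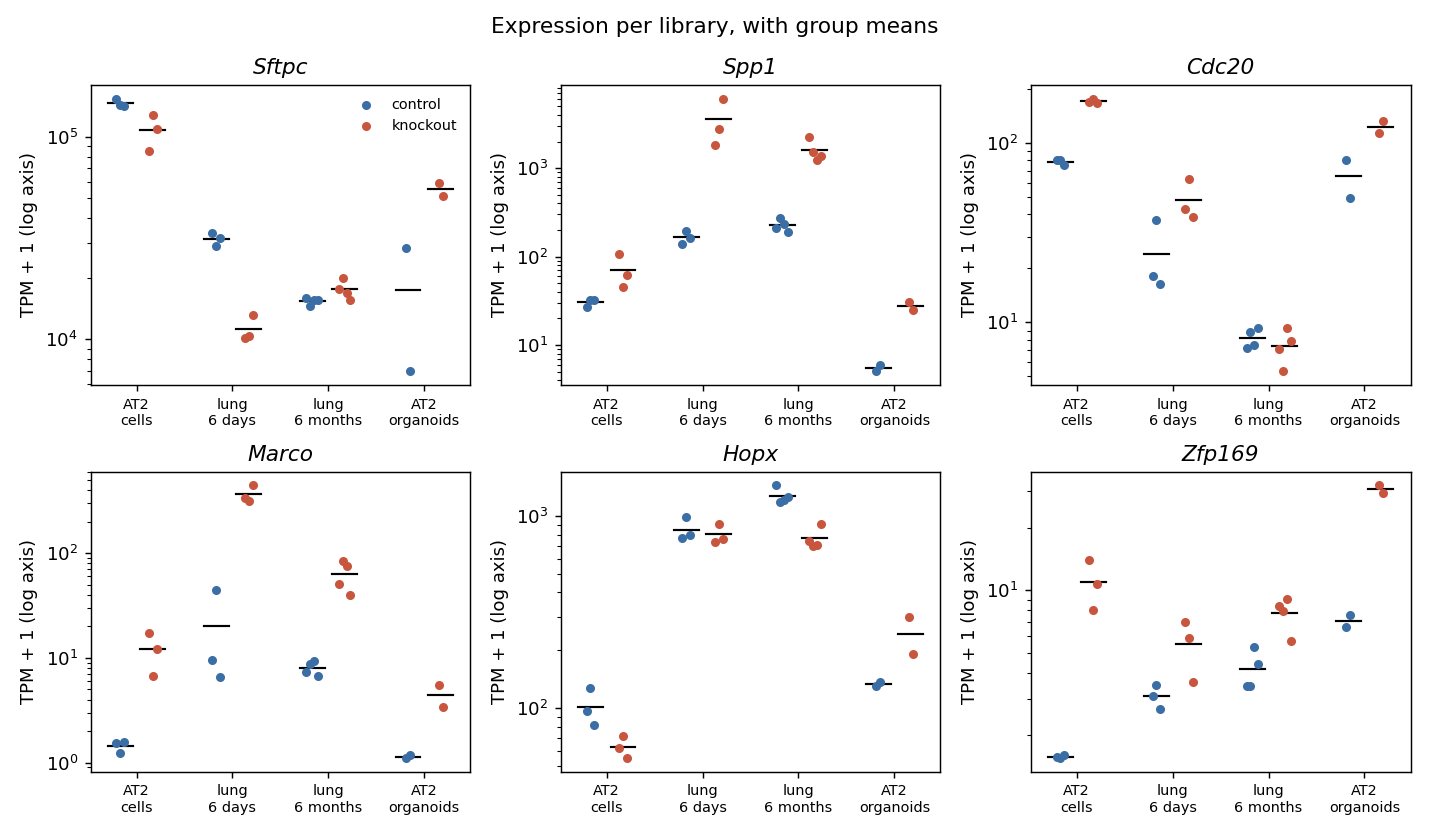
TPM + 1 on a log axis of 6 genes in every library of the 4 kinds of sample, with controls in blue, knockouts in red and black bars at the group means of TPM + 1. Marco and Spp1 lie higher in the knockout libraries of both lung time points, Cdc20 rose in sorted AT2 cells (77.6 to 170.4 TPM), and Zfp169 lies higher in every knockout library than in every control of its own sample kind.

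In AT2 organoids after 14 days of culture, the comparison asked how the cultures differed by genotype. Basal cell keratins were far lower in knockouts, and a change within AT2 cells cannot be told from a different mix of cells. Krt5 fell from 1121 ± 566 to 57.4 ± 3.48 TPM (SD, n = 2), Krt14 from 67.7 ± 13.3 to 1.60 ± 0.126 TPM and Krt17 from 140.8 ± 47.9 to 5.33 ± 0.741 TPM. The inhibitors of DNA binding Id3 (5.78 ± 0.830 to 186 ± 7.67 TPM), Id1 (2.11 ± 0.14) and Id2 (1.54 ± 0.11), which act downstream of BMP and TGF-beta signals, rose. The 2 control cultures differed from each other, with Sftpc at 28199 and 6935 TPM, and Sftpc did not pass (1.98 ± 0.72, adjusted p 0.131). It passed without control 1 (3.0) or without control 2 (0.97).

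Of 10 basal cell genes, 0 rose, 5 fell and 5 did not pass (0 rose and 10 fell when adjusted over the list alone). For basal cell genes, the median was −3.64 (camera adjusted p 4e-08, and adjusted p = 0.902 with an estimated correlation). Of 12 ciliated cell genes, 0 passed by limma (0 rose and 12 fell when adjusted over the list alone), and 0 had positive values. For ciliated cell genes, the median was −1.91 (camera adjusted p 2.7e-07, and adjusted p = 0.902 with an estimated correlation). Of 15 club cell genes, 0 rose, 2 fell and 13 did not pass (2 rose and 11 fell when adjusted over the list alone). For club cell genes, the median was −1.01 (camera adjusted p 0.000954, and adjusted p = 0.902 with an estimated correlation). Haptoglobin, Hp (−1.43 ± 0.10), and Scgb3a1 (−2.25 ± 0.21) fell. Of 40 cell cycle genes, 0 passed by limma (35 rose and 0 fell when adjusted over the list alone), and 40 had positive values. For cell cycle genes, the median was 0.83 (camera adjusted p 4.27e-09, and adjusted p = 0.952 with an estimated correlation). Of 25 AT1 markers, 1 rose, 0 fell and 24 did not pass (12 rose and 2 fell when adjusted over the list alone). For AT1 markers, the median was 0.83 (camera adjusted p 0.00856, and adjusted p = 0.902 with an estimated correlation). Igfbp2 (3.42 ± 0.25) rose and Hopx (0.83 ± 0.24, adjusted p 0.0929) did not pass, and the AT1 call ended without control 1 (adjusted p 0.0761) and with a filter at 5 TPM (0.0973). Of 30 AT2 identity and surfactant genes, 0 passed by limma (the same counts when adjusted over the list alone), and 24 had positive values. As a list, AT2 identity and surfactant genes did not pass (camera adjusted p 0.0929). That list passed as higher without control 1 (5.12e-06) or knockout 2 (0.00823), after median-ratio scaling (0.0297), with library weights (0.0172) and with the replicate block (0.00937). Of 27 glycolysis and hypoxia genes, 0 rose, 1 fell and 26 did not pass (0 rose and 17 fell when adjusted over the list alone). For glycolysis and hypoxia genes, the median was −0.94 (camera adjusted p 4e-08, and adjusted p = 0.902 with an estimated correlation). The glucose transporter Slc2a1 (−1.39 ± 0.10) fell. Of 18 AP-1 and immediate early genes, 0 passed by limma (0 rose and 7 fell when adjusted over the list alone), and 3 had positive values. For AP-1 and immediate early genes, the median was −0.79 (camera adjusted p 0.00162, and adjusted p = 0.902 with an estimated correlation). Of 28 MHC class II and interferon genes, 0 passed by limma (0 rose and 5 fell when adjusted over the list alone), and 3 had positive values. For MHC class II and interferon genes, the median was −0.43 (camera adjusted p 0.00134, and adjusted p = 0.902 with an estimated correlation). The MHC class II call ended without control 1 (adjusted p 0.409). Of 35 MYC target and ribosome biogenesis genes, 0 passed by limma (the same counts when adjusted over the list alone), and 32 had positive values. Their median was 0.60 (camera adjusted p 5e-05, and adjusted p = 0.97 with an estimated correlation).

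Of 41 reported let-7 targets, 0 passed by limma (3 rose and 0 fell when adjusted over the list alone), and 26 had positive values. As a list, reported let-7 targets did not pass (camera adjusted p 0.456). Igf2bp1 (1.41 ± 0.19, adjusted p 0.06) did not pass. Neither did Ezh2 (0.67 ± 0.11, adjusted p 0.0668), nor Hmga2 (−1.85 ± 0.63, adjusted p 0.119), Myc (−0.57 ± 0.24, adjusted p 0.169), Bach1 (−0.32 ± 0.14, adjusted p 0.17) and Krt8 (0.01 ± 0.11, adjusted p 0.97). Without control 1, Hmga2 (−2.74), Ezh2 (0.67) and Myc (−0.82) passed, and without control 2, Hmga2 (−0.96), Ezh2 (0.68) and Bach1 (−0.44). Igf2bp3 and Lin28b lay below the filter. Of 18 collagen and matrix genes, 2 rose, 1 fell and 15 did not pass (5 rose and 4 fell when adjusted over the list alone). As a list, collagen and matrix genes did not pass (camera adjusted p 0.781). Sparc (2.13 ± 0.14) and Spp1 (2.34 ± 0.17) rose and Col16a1 (−1.8 ± 0.16) fell. Among genes named for size, the transcription factor gene Atoh8 (4.24 ± 0.23), Cltrn (3.1 ± 0.18), Palm3 (2.82 ± 0.25) and R3hdml (2.72 ± 0.20) rose. Ly6d (−5.01 ± 0.16), the lysophospholipase Enpp2 (−4.44 ± 0.14) and the keratin Krt15 (−3.82 ± 0.24) fell.

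By limma, 27 genes rose and 48 fell of 12406 tested in organoids (2439 and 2088 at an unadjusted p under 0.05; 36% of calls higher, and 46.4% after quantile normalization), and the genotypes did not overlap in 8889 genes (71.7%, where chance gives 33.3% with 2 against 2). The counts were 0 and 0 without the filter and without knockout 1 or knockout 2, where all 24 named genes lost their calls, and rose to 3739 and 3228 without control 1 and 1475 and 1696 without control 2. In each of these fits the lone library was assumed to vary like the other genotype.

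**Figure D2:**
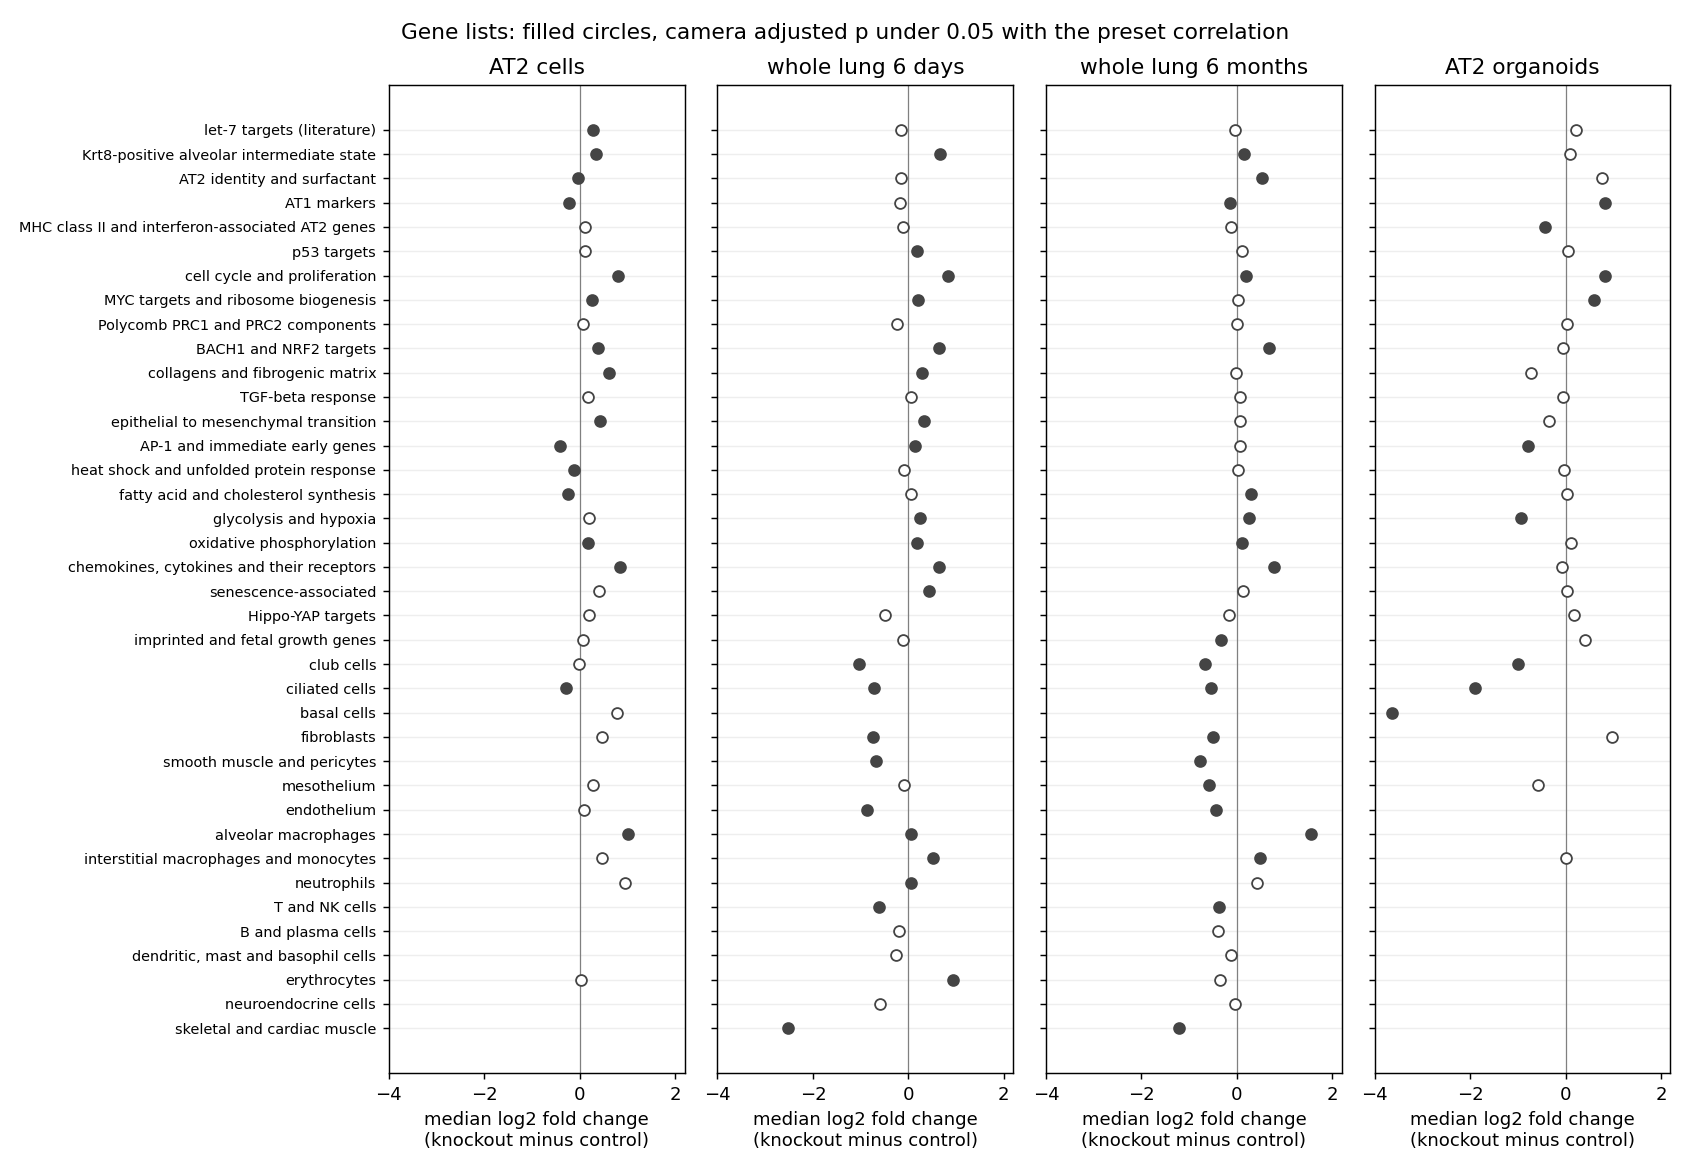
Median log2 fold change of the members of each gene list, knockout against control, in the 4 kinds of sample; filled points passed camera with the preset correlation (adjusted p under 0.05), and none passed with an estimated correlation. The muscle genes lie lowest in lungs at 6 days (median −2.53) and the basal cell genes in organoids (median −3.64).

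The whole-lung comparisons were set against each other to ask which effects differed between 6 days and 6 months. Of 13875 genes, the knockout effect was higher at 6 months in 524 and lower in 86. Mmp12 (difference 5.06 ± 0.61 SE), Bex1 (4.27 ± 0.44) and Gpnmb (4.05 ± 0.44) were higher. Arg1 (−4.12 ± 0.55), the activin inhibitor Fst (−2.29 ± 0.34) and Slurp1 (−2.25 ± 0.43) were lower. The effect on Sftpc was higher at 6 months by 1.67 ± 0.15 (limma adjusted p 5.71e-05), and that on Krt8 lower (−0.78 ± 0.17, adjusted p 0.0209). Hopx was also lower (−0.66 ± 0.17, adjusted p 0.0357), but not with a separate spread for each table (0.0607), nor without 6-day control 1 (0.109), control 3 (0.108) or knockout 2 (0.0798), 6-month controls 1 to 4 (0.0765, 0.0553, 0.0539 and 0.0618) or 6-month knockouts 1 to 3 (0.0774, 0.0797 and 0.0736). The AT2 identity list differed (camera adjusted p 1.11e-12, higher at 6 months; adjusted p = 0.221 with an estimated correlation), as did the cell cycle list (4.77e-14, lower; adjusted p = 0.483 with an estimated correlation). The 6-month lungs expressed Xist with Ddx3y at 0 in all 8 libraries and all other libraries expressed Ddx3y, and the sex of the mice thus differed along with the time of tamoxifen and the age, and this comparison does not separate them. The 524 and 86 genes became 293 and 35 without 6-day control 1, 299 and 39 without 6-day control 3, 1285 and 155 without 6-day knockout 1. They became 314 higher without 6-month control 2 and 312 and 50 without 6-month knockout 1. The lower count became 141 without 6-day control 2, 344 without 6-day knockout 3, 51 without 6-month control 3 and 53 without 6-month knockout 2. With a separate spread per table, an alternative added after the data were seen, they were 330 and 49.

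Organoids and freshly sorted AT2 cells were compared in the same way. Of 11351 genes, the effect was higher in organoids in 661 and lower in 943. Igfbp2 (difference 4.64 ± 0.39), Id3 (4.50 ± 0.30) and Atoh8 (4.30 ± 0.23) were higher. Orm1 (−5.87 ± 0.43), Krt14 (−5.56 ± 0.58) and Ly6d (−5.48 ± 0.41) were lower. Hopx also differed (1.51 ± 0.31, limma adjusted p 0.0164, but not without organoid knockout 1, where it was 1.2). The cell cycle list did not differ (medians 0.81 and 0.83, camera adjusted p 0.926), while the glycolysis and hypoxia list did (medians 0.19 and −0.89, camera adjusted p 1.99e-09, and adjusted p = 0.398 with an estimated correlation). The counts became 1921 and 1787 without organoid control 1, 401 higher without organoid control 2, 87 and 234 without organoid knockout 1 and 87 and 196 without organoid knockout 2. Without AT2 controls 1, 2 and 3 the higher count was 379, 251 and 322, and without AT2 knockouts 2 and 3 it was 413 and 325. The lower count was 549, 568 and 568 without AT2 control 2, control 3 and knockout 3. With a separate spread per table, the effect was higher in 365.

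Shared calls were tested by Fisher's exact test, which takes genes that move together as independent, and no library was shared between comparisons. Of the genes tested in both, 108 rose in AT2 cells and in lungs at 6 days, where 21.9 would be shared by independent lists (odds ratio 7.78, adjusted p 5.92e-47), and 33 fell in both (expected 3.34). Lungs at 6 days and 6 months shared 350 risen genes (expected 67.0, odds ratio 31.4) and 349 fallen genes (expected 72.0). AT2 cells and lungs at 6 months shared 264 (expected 119) and 46 (expected 14.8). Organoids shared 3 risen genes with AT2 cells (expected 1.24, adjusted p 0.149) and 0 fallen genes (expected 0.403), and 5 genes that rose in AT2 cells fell in organoids. With a threshold of 0.1 they shared 384 risen genes (expected 189, adjusted p 1.45e-49), and 114 that rose in AT2 cells fell in organoids. Organoids shared 8 risen genes with lungs at 6 months (expected 3.24, odds ratio 3.38, adjusted p 0.0169) and 3 fallen genes (expected 3.74), while 11 that rose at 6 months fell in organoids. With a threshold of 0.1 the odds ratio of risen genes was 1.19, with 330 shared, and 252 that rose at 6 months fell in organoids. Spp1 rose in all 4 comparisons, 63 genes rose in 3 of them and 15 fell in 3, of 11126 tested in all 4. The let-7 8mer genes differed from genes without a site by −0.01, 0.03 and 0.02 in mean log2 fold change in lungs at 6 days, lungs at 6 months and organoids, and 0, 3 and 32 of 100 shuffled 8mers gave a difference as high. The median differences of the shuffled 8mers were −0.09, −0.029 and −0.004, and the camera p values were 0.721, 0.782 and 0.981. With 7mer sites counted too, the differences were 0.033 in AT2 cells and −0.025, 0.01 and 0.049 in the other comparisons in that order, and 0, 0, 0 and 2 of 100 shuffled sites gave a difference as high.

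Zfp169, a zinc finger gene singled out after its values were seen, lies beside the deleted microRNAs on chromosome 13 (GRCm38, 48487647 to 48513451, minus strand), next to Mirlet7d (48536012 to 48536114), Mirlet7f-1 (48537829 to 48537917) and Mirlet7a-1 (48538179 to 48538272). It rose from 0.580 ± 0.0329 to 9.94 ± 2.99 TPM in AT2 cells (2.75 ± 0.20, limma adjusted p 0.00207), from 3.17 ± 0.907 to 6.78 ± 1.46 TPM in lungs at 6 months (0.90 ± 0.18, adjusted p 0.00303) and from 6.14 ± 0.690 to 29.7 ± 1.91 TPM in organoids (2.10 ± 0.14, adjusted p 0.0317). In lungs at 6 days it did not pass (0.79 ± 0.27, adjusted p 0.117), and did after median-ratio scaling (0.89), quantile normalization (0.96), library weights (0.97) or without knockout 3 (1.07). In organoids it did not pass without the filter, without knockout 1 (2.04) or without knockout 2 (2.17).

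**Figure D3:**
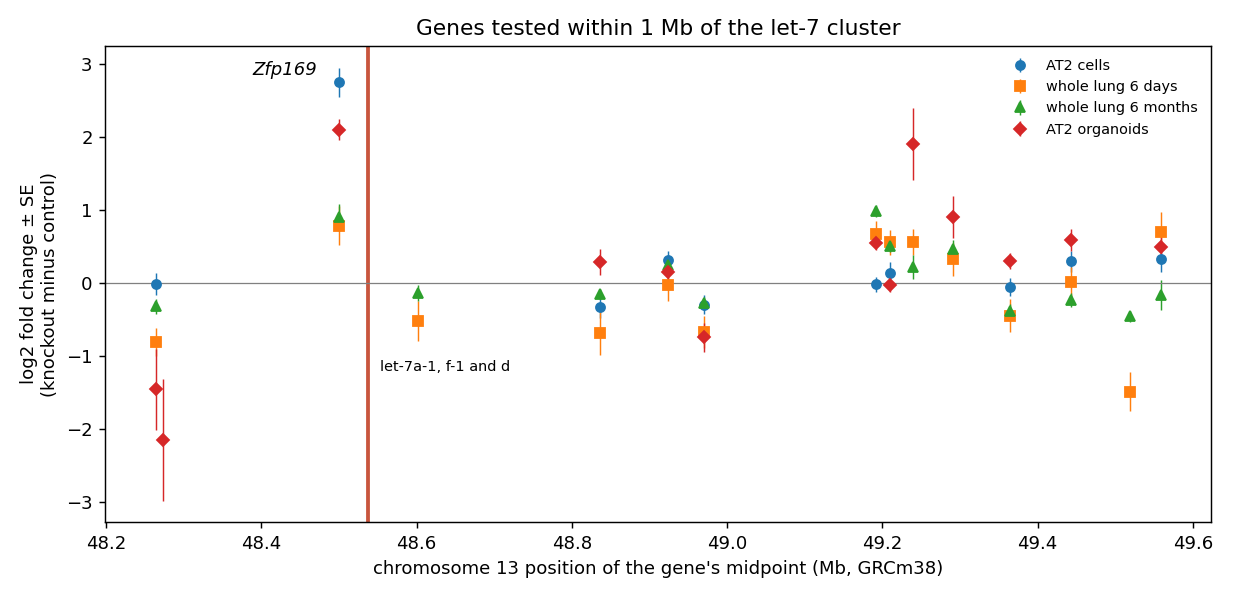
Log2 fold change (points) with its SE (bars) of the genes tested within 1 Mb of the deleted microRNA cluster, against the midpoint of each gene on chromosome 13 in Mb (GRCm38), in the 4 kinds of sample; the red bar marks the cluster. Zfp169 has the highest value in AT2 cells (2.75), and of the other 9 genes tested there in AT2 cells 0 passed by limma.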

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

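The tests of regional DNA and of removal of the let-7 DNA at Zfp169, of leukocyte RNA in the sorted cells and of resident cells in the 6-day lungs were chosen only after the results were seen, as was the separate spread for each table.

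Zfp169, the gene 22.6 kb from the deleted cluster, was higher in knockouts in AT2 cells, organoids and lungs at 6 months. A let-7 site in its 3′ UTR is argued against, since 0 site types were found in 1795 bases. Other DNA around the engineered locus stays open: of 39 other genes tested within 5 Mb, 5.13% passed in AT2 cells against 7.85% of all genes, but the exact 95% upper bound was 17.3%, and at 6 months 46.9% of 49 such genes passed against 29.8% (Fisher's exact p 0.0118). The reading of the AT2 share as open, by that bound, was set after its value was seen. Removal of the let-7 DNA itself, with Zfp169 higher in 3 comparisons, may act on this gene and cannot be told apart from loss of the microRNAs, since every knockout library carries both.

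Macrophage genes were higher in the sorted AT2 knockout cells, with 6 of 13 alveolar macrophage markers passing. Their median was 0.96 after median-ratio scaling, whose factors (0.95 to 1.05) were too small to remove it. A candidate source is RNA of macrophages or other leukocytes among the sorted cells: the median of 13 general leukocyte genes tested, of 16 listed, was 1.36 (6 passed and 12 lay above the median of all genes), with Laptm5 at 4.77 and 15.5 TPM and Chil3 at 25.9 and 146 TPM. The cells were sorted by flow cytometry, but the gate is not given in the sources used here. Whether AT2 cells themselves express these genes after loss of let-7 was not tested and stays open.

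Heart muscle genes were lower in the knockout lungs at 6 days, with all 11 tested genes passing. Median-ratio scaling (factors 0.76 to 1.10) could not remove this (median −2.38). An equal fall of all resident cells could explain at most part, since 54 endothelial, fibroblast and smooth muscle markers had a median of −0.73 against −2.53. Heart and fat pieces taken along with some lungs may contribute, which stays open. Fat genes had medians of −2.81 at 6 days (10 of 10 passed) and −0.70 at 6 months, between preset bounds. Muscle genes fell at 6 months too (10 of 11, median −1.22). A biological difference in muscle within the lung was not tested.

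The difference between the 6-month and the 6-day knockout effect passed in 524 genes upward and 86 downward, and that between organoids and AT2 cells in 661 and 943. In the whole-lung difference the genes were Mmp12 (5.06), Bex1 (4.27), Gpnmb (4.05), Arg1 (−4.12), Fst (−2.29), Slurp1 (−2.25), Sftpc (1.67), Hopx (−0.66) and Krt8 (−0.78). In the other they were Igfbp2 (4.64), Id3 (4.50), Atoh8 (4.30), Orm1 (−5.87), Krt14 (−5.56), Ly6d (−5.48) and Hopx (1.51).

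Other splits of the libraries were counted for these fits. In AT2 cells the real split called 950 genes and the highest of the others 0, and in lungs at 6 days 983 and 0; in both, 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. In lungs at 6 months 1 of 35 unpaired splits, the real one with 4226 genes, gave as many, the lowest share possible, and the highest other called 1. For the whole-lung difference, 2 of 100 splits drawn of 700 gave as many as the real 610; the other called 1312. That split kept the 6-day genotypes apart and so still held the 6-day knockout effect, as did 7 others, which called 9 to 136. Another 1 kept the 6-month genotypes apart and called 215, and the 90 splits that mixed the genotypes in both tables called at most 1.

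In lungs at 6 months, 11 of 158 groups of 4 libraries held a library past Dixon's 95% critical value, where chance gives about 1 in 20. Among controls these were Cdkn1c in control 3 (42.55 TPM; others 39.24 to 39.7), Chil1 in control 3 (813.3; 771.3 to 774.1), Cst8 in control 1 (24.25; 15.64 to 16.56) and Ctsk in control 2 (18.28; 23.31 to 24.03). Among knockouts they were Chil1 in knockout 2 (3343; 2734 to 2787), Igfbp6 in knockout 3 (103.1; 126.7 to 130.6), Myc in knockout 1 (11.59; 14.49 to 14.81), Myh6 in knockout 1 (43.1; 24.55 to 27.63), Pcna in knockout 3 (142.9; 150.8 to 151.2), Pgam1 in knockout 3 (200; 228.9 to 231.9) and Tagln in knockout 4 (135.3; 125.2 to 126.8).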

How the results depend on the processing

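The separate spread for each table was chosen only after the data were seen; the other alternatives were planned. The cause of the changes below was not tested, except that the leave-one-out fits hold fewer libraries.

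The 6-month counts stayed within 1.5 times under every alternative run (1860 to 2295 higher and 1555 to 1923 lower when 1 library was left out). In AT2 cells the counts were 340 higher and 30 lower without the filter, 443 higher after median-ratio scaling, 401 higher after quantile normalization and 86 lower without a variance trend, and 181 to 929 higher and 6 to 285 lower in the leave-one-out fits. In lungs at 6 days they were 323 lower with a filter at 5 TPM, 906 and 883 after median-ratio scaling, 922 and 966 after quantile normalization, 3858 and 4537 with library weights, and 41 to 1032 higher and 51 to 1017 lower in the leave-one-out fits. In organoids they were 0 and 0 without the filter, 232 and 427 with library weights, 67 and 116 without a variance trend, and 0 to 3739 higher and 0 to 3228 lower in the leave-one-out fits, where the lone library was assumed to vary like the other genotype.

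The replicate block gave 344 lower genes in lungs at 6 days and 122 higher and 277 lower in organoids, against 2376 and 2078 in lungs at 6 months. The labels state no pairing; at 6 months all 4 controls and all 4 knockouts lay closest to the library of their own number.

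The let-7 target list in AT2 cells lost its call with an estimated correlation (adjusted p 0.752) and with fry (0.0701), and kept it in the leave-one-out fits (0.00143 to 0.0198). The endothelial list in AT2 cells reversed without control 1 (adjusted p 0.000648; leave-one-out range 0.000648 to 0.744), and Esam in organoids reversed without control 2 (log2 fold change −0.74; range −0.74 to 1.52).

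The whole-lung difference had 241 lower genes after median-ratio scaling, 330 higher and 49 lower with a separate spread, and 293 to 1285 higher and 35 to 344 lower in the leave-one-out fits. The organoid difference had 365 higher genes with a separate spread, and 87 to 1921 higher and 196 to 1787 lower in the leave-one-out fits. At an adjusted p of 0.1 in both, the odds ratios of shared calls with organoids were 2.89 (higher) and 1.91 (lower, from 0) for AT2 cells, 2.19 and 3.50 for lungs at 6 days, and 1.19 (higher, from 3.38) and 2.47 (lower, from 0.783) for lungs at 6 months. Depth is unknown, so what it limits could not be computed.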

Other observations

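The gene lists in this part were chosen only after values were seen, and no explanation was tested for them.

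Of 20 lysosome genes, 11 rose in AT2 cells, 16 in lungs at 6 days and all 20 in lungs at 6 months by limma, and 0 of 19 tested passed in organoids, where 9 had positive values. Of these genes, Ctsk and Atp6v0d2 are also in the list of alveolar macrophage markers, whose median was 1.02 in AT2 cells, 0.06 in lungs at 6 days and 1.55 in lungs at 6 months. Of the general leukocyte genes, 6 of 13 tested rose in AT2 cells, and 5 of 16 and 13 of 16 in lungs at 6 days and 6 months (medians 1.36, 0.35 and 0.76). At 6 months Ctsd rose from 612.5 ± 23.0 to 5772 ± 603 TPM (SD, n = 4) and Cd68 from 50.6 ± 4.88 to 758 ± 77.4 TPM. Of 18 clock genes 11 rose and 2 fell at 6 months, 1 rose and 2 fell at 6 days, and of 17 tested 0 rose and 2 fell in AT2 cells and 0 rose and 1 fell in organoids (medians 0.66, −0.2, 0.13 and −0.57). At 6 months Arntl was lower (−1.63 ± 0.17 SE) and Dbp (1.54 ± 0.16) and Bhlhe41 (2.04 ± 0.18) were higher. Arntl also fell in AT2 cells (−0.74 ± 0.17) and in lungs at 6 days (−0.95 ± 0.20), and did not pass in organoids (0.07 ± 0.17). Bhlhe41 also rose in lungs at 6 days (1.51 ± 0.20), fell in organoids (−1.93 ± 0.18) and did not pass in AT2 cells (0.62 ± 0.17), and Dbp passed in none of these 3 comparisons (0.57 ± 0.54, −2.13 ± 0.40 and 1.16 ± 0.40). The hours at which tissue was taken are not given in the sources used here.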
